A study of Mus musculus with 6 samples.

How the data were processed

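The series holds 6 libraries of frontal lobe nuclei, 1 per mouse, from Tg-SwDI mice that were Trem2 wild type (3) or Trem2 knockout (3). Per the labels' protocols, nuclei were isolated from tissue by detergent lysis and mechanical dissociation without permeabilization and taken through droplet-based 3′ single-cell RNA chemistry. Replicates are numbered within a genotype in accession order, which pairs no samples. Each library is a deposited matrix of raw UMI counts per gene and barcode for 32285 genes, limited to barcodes that the authors' software had called as nuclei. The counts came from Cell Ranger, version 6.1.2 in 5 libraries and 7.0.0 in knockout replicate 1, per the file headers. The submitters' processing notes name mm10, Cell Ranger and Seurat; whether intronic reads were counted, and the annotation release, are not given in the sources used here.

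Barcodes with at least 200 detected genes and at most 5% mitochondrial UMIs were kept, 34281 of 39752. That limit removed 15.5%, 17.8% and 6.33% of barcodes in wild type replicates 1 to 3 and 4.62%, 9.48% and 29.99% in knockout replicates 1 to 3. Doublets were called in each library with Scrublet in scanpy 1.11.5 at an expected rate of 6%, and 1273 were removed. Median UMIs per remaining nucleus were 1444, 2103 and 2114 in wild type and 5310, 1705 and 2465 in knockout. Counts were log-normalized, 2000 variable genes were ranked within libraries, values were scaled within each library, and 30 principal components and 15 neighbours gave 63 Leiden clusters at resolution 1 (leidenalg 0.10.2, seed 1). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

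Clusters of at least 20 nuclei were named from marker genes chosen before the data were examined, as were the tests, the gene lists and the rule for named genes. A name needed at least 3 markers with a mean log2 fold of 0.8 over other nuclei (pseudocount 20 CPM) and an own marker among the top 50 genes. It was withheld when a gene of other brain regions, or as many markers of another class, stood among the top 10. These thresholds were set after seeing the data. They gave microglia-like, astrocyte-like, oligodendrocyte-like, oligodendrocyte precursor-like, excitatory neuron-like, inhibitory neuron-like and striatal projection neuron-like classes, plus small border macrophage-like, fibroblast-like, mural-like and endothelial-like ones; the text drops the suffix. The thresholds left 43.9%, 24.6% and 39.0% of wild-type and 31.9%, 30.1% and 35.2% of knockout nuclei unnamed. A difference from the authors' own annotation, not used here, may come from these rebuilt names.

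UMI counts were summed per library and class, for classes with at least 20 nuclei in every library, and for all nuclei together. The mouse was the replicate, and nuclei were not treated as replicates. Genotypes were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr, two-sided), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. Normalized CPM are on the TMM scale, and means carry the SD over 3 libraries. Class sums ranged from 95186 UMIs (astrocytes) to 17618554 (excitatory neurons) per library. Whether the genotype effect differed between astrocytes and oligodendrocytes, or between excitatory and inhibitory neurons, was tested with a class by genotype term and the mouse as a block. Of the fixed gene lists 27 had at least 5 tested members in some class; they were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over all 136 tests, beside camera with an estimated correlation and fry. In 16 of those tests the sign of the list's median differed from that of the test, none of them called. Class shares and microglial scores were compared with an exact permutation test over the 20 assignments of 6 libraries, two-sided, whose smallest p is 0.1. Scores were the percent of microglial UMIs from a list, and the number of its genes detected after thinning nuclei to 1000 UMIs, which left out nuclei with fewer.

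The text names Trem2 and its gene cluster, the 5 smallest p in a class without calls (except unnamed-locus, mitochondrial and sex-linked genes), up to 4 members of each list with the smallest p, and App and Apoe where expressed. Some genes that this rule selects are not reported. Lists described in the text are those that passed over 6 or 5 libraries and those about microglial and oligodendrocyte states. Other genes were chosen after their values were seen: Gm26917, Sst, Npy, Crhbp in inhibitory neurons, Rbfox1, Malat1, Hba-a1, Pla2g7, A930015D03Rik, Hbb-bs, Cxcl10, C4a, H2-T24 and the genes called by the interaction test. Gene positions, strands and intron bases came from the GENCODE M21 annotation of the mm10 assembly, in which 32235 of the 32285 identifiers matched (99.85%).

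Each test was tried on simulated counts drawn from the real means and library sizes with known changes. All genes of a simulation shared a common spread, and their means were alike in every library. Spread that differs between genes and the shift of knockout replicate 1 were therefore not modelled. In the real fits Anapc15 in microglia (4.24-fold) and Trim33 in astrocytes (5.04-fold) did not pass. The absence of calls thus does not exclude 4-fold changes. Over 6 libraries the share of 4-fold changes recovered was 75.6% in microglia, 71.4% in astrocytes, 78.0% in oligodendrocytes, 59.3% in oligodendrocyte precursors, 40.6% in excitatory, 59.3% in inhibitory and 42.4% in striatal neurons, and 55.1% over all nuclei. The share of 2-fold changes recovered was at most 9.57% in these comparisons. Over the 5 libraries of one version it was 81.7% to 97.9% of 4-fold changes. For the interaction tests it was 60% of 4-fold changes between astrocytes and oligodendrocytes and 87% between excitatory and inhibitory neurons. A simulated changed list had a camera adjusted p of 2.25e-15 with the preset and 0.188 with an estimated correlation. The latter thus had little power with 3 libraries per genotype. The simulated genes were drawn independently, so they cannot show whether the preset holds for genes that vary together.

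Alternatives were DESeq2 1.42.0, other size factors (RLE), no filter on low counts, doublets kept, a stricter filter on nuclei (at least 500 genes and at most 2% mitochondrial UMIs), thinning to the smallest total, resolution 2 (71 clusters), the omission of sex-linked genes, and leaving out each library. Chosen after seeing the data were DESeq2 on the 5 libraries of one version, genes with under 2000 intron bases, and the omission of wild type replicate 1 and knockout replicate 2, which were rich in an unnamed inhibitory cluster. Endothelial and mural nuclei were fewer than 20 in some libraries and were not tested.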

Results

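Nuclei from the frontal lobe of 6 Tg-SwDI mice were profiled by droplet-based single-nucleus RNA sequencing, which counts the 3′ ends of transcripts with unique molecular identifiers (UMIs). Tg-SwDI mice carry a human amyloid precursor protein transgene with the Swedish, Dutch and Iowa changes and develop cerebral amyloid angiopathy, the deposition of amyloid in brain vessels. Trem2, which encodes a lipid-sensing receptor of microglia, was wild type in 3 of the mice and knocked out in the other 3. The comparison asks which transcripts differ in each cell class when Trem2 is lost in a brain with vascular amyloid. The libraries held 39752 barcodes, from 5220 in knockout replicate 2 to 8095 in knockout replicate 1. The series states 5700 to 8100 nuclei per sample, so 1 library lay below the stated range. Total UMIs were 51317961 in knockout replicate 1 and between 11493087 and 17835287 in the other 5 libraries. After filtering and removal of doublets 33008 nuclei remained, from 4427 in knockout replicate 3 to 7460 in knockout replicate 1. Clusters with the markers of microglia, astrocytes, oligodendrocytes, oligodendrocyte precursors, excitatory neurons, inhibitory neurons and striatal projection neurons were compared between genotypes under those names.

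Knockout replicate 1 stood apart from the other 5 libraries in the kind of transcript it counted. Its counts came from Cell Ranger 7.0.0 and those of the other 5 libraries from 6.1.2. In oligodendrocytes the median log2 ratio of knockout replicate 1 to the other libraries rose from -0.88 in the group of genes with the fewest intron bases to 0.93 in the group with the most, a difference of 1.81 (5 groups of equal size). That difference lay between -0.21 and 0.26 in the other 5 libraries, each set against the rest without knockout replicate 1. Rbfox1, a neuronal splicing factor with 1521772 intron bases, had 4634 CPM (UMIs of a gene per 1e6 UMIs) over all nuclei in knockout replicate 1 and 107 to 141 elsewhere. Malat1, an intronless nuclear RNA, had 90653 CPM there and 180212 to 295379 elsewhere. Its mean correlation of log CPM across genes with the other 5 libraries was 0.787, against 0.964 to 0.982 among those 5; genes are not independent replicates. Each comparison is therefore given over all 6 libraries and, where it matters, over the 5 libraries of one software version (3 wild type and 2 knockout).

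**Figure D1:**
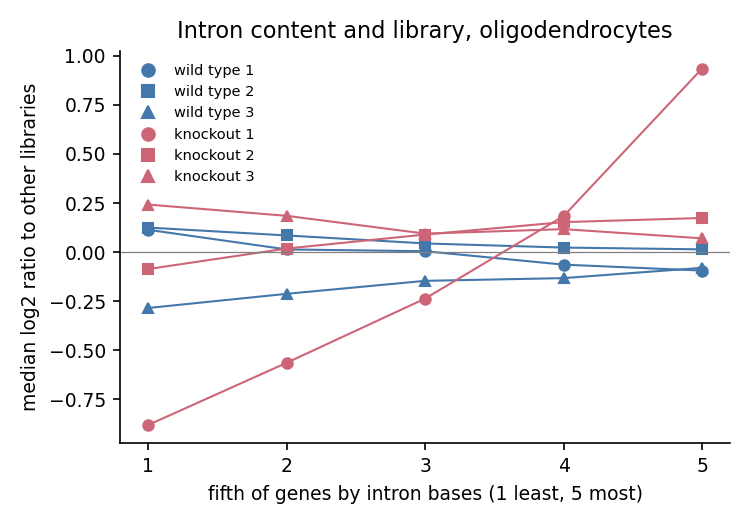
Median log2 ratio of each library's CPM to that of the other libraries in oligodendrocytes (vertical axis) for genes sorted into 5 groups by annotated intron bases (horizontal axis); each line is 1 library. Knockout replicate 1 was set against the other 5 libraries, and each of these 5 against the rest without knockout replicate 1. Knockout replicate 1 climbs from -0.88 to 0.93, and the other 5 libraries differ by at most 0.26 between the first and the last group.

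Trem2 (ENSMUSG00000023992; mm10 chromosome 17, 48346401 to 48354147, plus strand), the targeted gene, was lower in the microglia of every knockout library than in those of every wild-type library. It measured 2002, 1727 and 1003 normalized CPM in wild type replicates 1 to 3 and 336, 774 and 506 in knockout replicates 1 to 3 (1578 ± 516 against 538 ± 221, SD, n = 3 each). The log2 fold change was -1.55 (SE 0.38; edgeR adjusted p = 0.776), and -1.27 without knockout replicate 1 (edgeR adjusted p = 0.0670). These values rest on 221, 143 and 154 Trem2 UMIs against 121, 132 and 90. Of the wild-type mean 34.1% remained, and 40.5% without knockout replicate 1. A 3′ count can come from a transcript that no longer encodes the receptor, and the labels do not describe the allele. At least 1 Trem2 UMI was found in 59.0%, 60.3% and 42.9% of wild-type microglia and in 29.7%, 37.2% and 27.5% of knockout microglia (median depth 678, 678, 682, 1396, 734 and 718 UMIs per nucleus in the same order). Excitatory neurons, which should lack the gene, had one in 1.66%, 1.27% and 0.450% of wild-type and 0.340%, 0.184% and 0.233% of knockout nuclei at 2643 to 8769 median UMIs. The neighbouring Trem-family genes Treml1, Treml2, Treml4, Trem1 and Trem3 had between 0 and 9 UMIs per library over all nuclei, too few to compare.

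**Figure D2:**
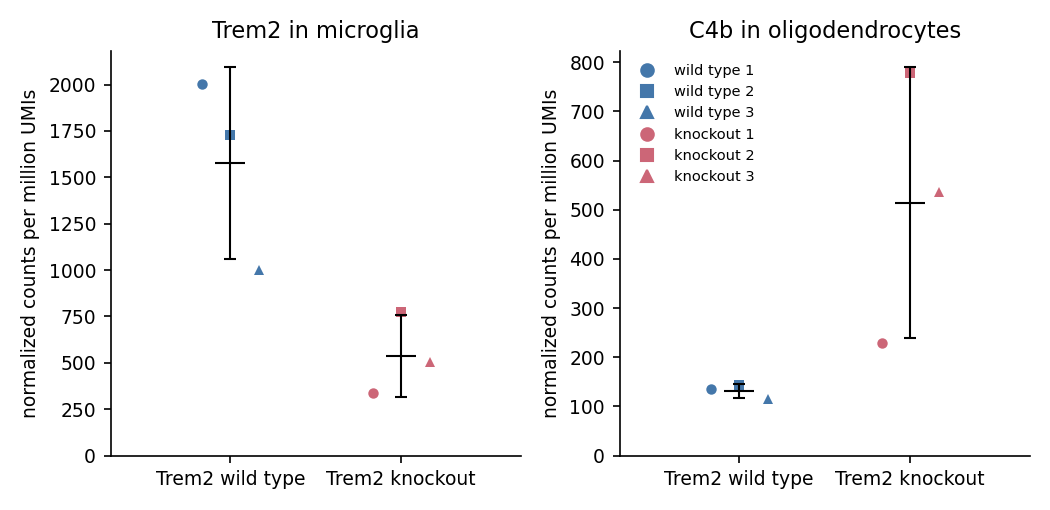
Normalized CPM of Trem2 in microglia and of C4b in oligodendrocytes (vertical axes) per library; symbols mark replicates, and black bars give the mean and SD of the 3 libraries of a genotype. Every knockout library lies below every wild-type library for Trem2 (336 to 774 against 1003 to 2002 CPM) and above every one for C4b (229 to 778 against 116 to 144 CPM).

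In microglia, interferon response genes and mitochondrial transcripts were the lists that passed. Over all classes, 8 of 10 splits of the libraries into equal groups called at least the 8 lists of the real split. The highest other split called 49, so a pass here and below is not by itself evidence of a genotype effect. Of 20 listed interferon genes only 5 had enough counts to test. Of these 4 were higher in the knockout, with a median log2 fold change of 0.76 (camera adjusted p = 0.0177, and 0.989 with an estimated correlation). Sp100, a nuclear body protein induced by interferon, measured 32.0 ± 4.55 CPM in wild type and 107 ± 19.0 in knockout (log2 1.71). Such values rest on few UMIs, since the microglial sum of a library was as low as 103345 UMIs. Trim30a measured 123 and 252 CPM (log2 0.99). Of the 5 members 2 passed when adjusted over the list alone and 0 over all genes, by edgeR. All 7 tested members were higher without knockout replicate 1 (median 0.97; camera adjusted p = 6.4e-06, and 0.996 with an estimated correlation), 4 of them passing when adjusted over the list alone. Outside the list, and chosen after its values were seen, the interferon-induced chemokine gene Cxcl10 went the other way, at 263, 24.2 and 91.2 CPM in wild type and 2.78, 17.6 and 5.62 in knockout. It entered the test only without knockout replicate 1 (log2 -3.38, edgeR adjusted p = 0.0503). All 10 mitochondrially encoded transcripts were lower (median -0.52; camera adjusted p = 0.000144; adjusted p = 0.989 with an estimated correlation), among them mt-Nd1 at 1258 ± 97.1 against 766 ± 127 CPM and mt-Nd3 at 417 ± 54.8 against 248 ± 35.3; in nuclei these transcripts are carry-over from cytoplasm. Ribosomal protein genes rose as well without knockout replicate 1, with 21 of 21 higher (median 0.54; camera adjusted p = 6.4e-06, and 0.996 with an estimated correlation).

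Of 29 listed genes that mark disease-associated microglia in dependence on Trem2, only 16 had enough counts to test. As a group these were not lower in the knockout. Of 16 tested members 13 were higher, with a median log2 fold change of 0.56 (camera adjusted p = 0.134), and without knockout replicate 1 the list rose, with 14 of 16 higher (median 0.40; camera adjusted p = 0.0120, and 0.996 with an estimated correlation). The rise was not limited to this list: in the same fit, beside the ribosomal protein genes, 17 of 19 lysosome genes (median 0.23; camera adjusted p = 0.0970) and 16 of 18 nuclear genes of oxidative phosphorylation (median 0.24; camera adjusted p = 0.477) were higher. The disease-associated genes that do not depend on Trem2 were higher in 6 of 8 over 6 libraries (median 0.13; camera adjusted p = 0.853) and in 8 of 8 without knockout replicate 1 (median 0.42; camera adjusted p = 0.0583). Trem2 itself belongs to the list and was 1 of the 3 lower members. Among the higher ones, Lilrb4a, an inhibitory receptor, measured 91.3 ± 26.0 against 170 ± 98.8 CPM (log2 0.88; 1.37 without knockout replicate 1), Serpine2, a protease inhibitor, 317 ± 67.8 against 490 ± 13.2 (0.64) and Timp2, a metalloprotease inhibitor, 213 ± 67.4 against 297 ± 91.3 (0.49). Arhgap24, Apbb2 and Cadm1 were high mainly in knockout replicate 1, with log2 fold changes of 1.91, 1.38 and 1.29 that were 0.58, 0.47 and 0.33 without it. The share of microglial UMIs from the list without Trem2 was 0.348% ± 0.0828 in wild type and 0.480% ± 0.0227 in knockout (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). The number of its genes detected per nucleus after thinning overlapped between genotypes, at 3.18, 2.50 and 2 in wild type and 3.58, 2.93 and 3 in knockout (exact permutation p = 0.3). Thinning kept only 11, 8 and 24 wild-type and 268, 43 and 25 knockout nuclei. Without thinning, at unequal depth, the numbers were 2.10, 2.25 and 1.57 against 4.38, 2.65 and 2.46 (exact permutation p = 0.1). Homeostatic microglial genes did not pass, with 12 of 18 lower (median -0.29, camera adjusted p = 0.203). Without knockout replicate 1 most of this fall was gone (12 of 18 lower, median -0.105, camera adjusted p = 0.532). Olfml3 measured 653 ± 159 against 381 ± 162 CPM (log2 -0.78) and Tmem119 632 ± 239 against 420.0 ± 77.5 (log2 -0.59). The share of microglial UMIs from the homeostatic list was 2.79% ± 0.291 against 2.41% ± 0.479 (exact permutation p = 0.2). It was lowest in knockout replicate 1 at 1.945%, and the knockout mean without that library was 2.64%. The number of its genes detected after thinning was 8.02 ± 1.88 against 9.33 ± 0.657 (exact permutation p = 0.4). App and Apoe had log2 fold changes of 0.16 and 0.15.

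No single gene passed in microglia over 6 libraries: edgeR called 0 of 4027 (252 with an unadjusted p under 0.05) and DESeq2 0. Beside Trem2, the smallest p belonged to Anapc15, a subunit of the anaphase-promoting complex, at 45.3, 48.3 and 84.7 CPM in wild type and 300.0, 316 and 169 in knockout (log2 2.08, SE 0.43), to Sp100, to Dnajc13, an endosomal chaperone (90.0 ± 15.2 against 235 ± 39.6 CPM, log2 1.37), and to Suclg2, a mitochondrial enzyme (44.1 ± 16.9 against 140 ± 55.8 CPM, log2 1.69), with an edgeR adjusted p of 0.776 each. Without knockout replicate 1 edgeR called 2 of 4442 genes, Anapc15 (log2 1.95, edgeR adjusted p = 0.0321) and the noncoding RNA Gm26917 (2.41, edgeR adjusted p = 0.00558). Gm26917 rested on 1 library, at 1720 CPM in knockout replicate 3 and 97.2 to 222 in the other 5, and its log2 fold change was -0.25 without that library.

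In oligodendrocytes, complement gene C4b stood out. C4b (ENSMUSG00000073418; mm10 chromosome 17, 34728380 to 34743882) encodes complement component 4 and is among the genes of disease-associated oligodendrocytes. It measured 135, 144 and 116 CPM in wild type and 229, 778 and 537 in knockout (132 ± 14.4 against 515 ± 275, SD, n = 3 each; log2 1.96, SE 0.43; edgeR adjusted p = 0.765). Over the 5 libraries of one version C4b rose by a log2 fold of 2.30 (SE 0.24; edgeR adjusted p = 0.000291) and was the 1 gene called of 8027. At least 1 C4b UMI was present in 9.51%, 9.59% and 7.22% of wild-type and 21.96%, 39.3% and 26.9% of knockout oligodendrocytes at median depths of 776 to 1598 UMIs. In excitatory neurons, at 2643 to 8769 UMIs, it was present in at most 0.447% of wild-type and 1.53% of knockout nuclei. Its near-identical copy C4a had 0, 0 and 1 UMIs in wild-type and 0, 3 and 1 in knockout oligodendrocytes, and how reads shared by both copies were assigned is not given in the sources used here. C4b lies 13.6 megabases from Trem2 on the same chromosome.

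C4b belongs to a list of disease-associated oligodendrocyte genes that was higher in 5 of 7 tested members (median 0.53; camera adjusted p = 0.0931; 1 passing when adjusted over the list alone, by edgeR). Over the 5 libraries of one version the list rose, with 8 of 9 members higher (median 0.57; camera adjusted p = 1.42e-05, and 0.996 with an estimated correlation) and 3 passing when adjusted over the list alone. C4b, picked from the same fit, counts in this test, so the test is no independent evidence of a wider change. Of the 9 members 6 lie outside chromosome 17, 5 of them higher, with a median of 0.56 without knockout replicate 1. Over 6 libraries 4 of these could be tested, with a median of 0.25. Il33, an alarmin cytokine, measured 215 ± 17.3 against 442 ± 212 CPM (log2 1.04), highest in knockout replicate 1 at 686, and had a log2 fold change of 0.55 without it. The class I histocompatibility gene H2-D1 measured 48.2 ± 18.6 against 108 ± 73.9 (log2 1.15), with 193 CPM in knockout replicate 3, 67.5 and 63.2 in the other knockout libraries, and a log2 fold change of 0.45 without replicate 3. Serpina3n, a secreted protease inhibitor, reached testable depth over 5 libraries only, with a log2 fold change of 2.11. Cholesterol synthesis genes fell as a group, with 11 of 14 lower (median -0.37; camera adjusted p = 0.0186; adjusted p = 0.989 with an estimated correlation), with a fall of the same size without knockout replicate 1 that missed the threshold (11 of 15 lower, median -0.37; camera adjusted p = 0.0596). Examples were Srebf2, the sterol-responsive transcription factor (144 ± 13.8 against 96.6 ± 9.85 CPM, log2 -0.58), and Sqle (36.1 ± 12.7 against 22.4 ± 0.836, log2 -0.69). Myelin genes had a median of 0.011, with a test pointing the other way (camera adjusted p = 0.929). Over 6 libraries edgeR called 0 of 7559 genes (474 with an unadjusted p under 0.05) and DESeq2 0. Next to C4b the smallest p were those of Tjap1 (98.5 ± 15.4 against 233 ± 45.8 CPM, log2 1.24) and Dlk2 (20.7 ± 8.48 against 74.9 ± 33.5, log2 1.83), both within 2.09 megabases of Trem2, Rhoj, a small GTPase (log2 2.21, and 1.24 without knockout replicate 1), and Ercc8, a DNA repair gene (log2 -1.24), each with an edgeR adjusted p of 0.765. App and Apoe had log2 fold changes of 0.14 and -0.064.

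In astrocytes, genes of cholesterol synthesis fell together. Of 13 tested members 12 were lower, with a median log2 fold change of -0.80 (camera adjusted p = 0.000789; adjusted p = 0.989 with an estimated correlation); without knockout replicate 1 it was 13 of 14 (camera adjusted p = 1.53e-05, and 0.996 with an estimated correlation), and 5 passed when adjusted over the list alone against 0 over 6 libraries. Msmo1, a sterol demethylation enzyme, measured 386 ± 140 in wild type and 191 ± 81.4 CPM in knockout (log2 -0.98), Cyp51 128 ± 21.4 and 65.7 ± 28.2 (-0.83), Hmgcs1, which makes the precursor of mevalonate, 178 ± 106 and 69.2 ± 50.1 (-1.21, and -1.50 to -0.64 with 1 library left out), and Insig1, the sterol sensor, 148 ± 82.5 and 67.4 ± 15.8 (-1.07). Mitochondrial transcripts fell too, 10 of 10 (median -0.30; camera adjusted p = 0.0177, and 0.989 with an estimated correlation), but the call was lost without knockout replicate 1 (9 of 10 lower, median -0.075; camera adjusted p = 0.548). Single genes did not pass: edgeR called 0 of 4257 (373 with an unadjusted p under 0.05) and DESeq2 0. Among the smallest p were those of Trim33, a ubiquitin ligase of TGF-beta signalling (16.5 ± 4.65 against 81.0 ± 21.9 CPM, log2 2.33), Pcsk6 (2.08), Hs3st3a1 (2.66; 2.16 to 3.34 with 1 library left out, and not testable without knockout replicate 1) and Etv5 (2.20), each with an edgeR adjusted p of 0.551. C4b was at 183 ± 48.6 against 154 ± 97.7 CPM in astrocytes (log2 -0.36, and 0.063 without knockout replicate 1), App had a log2 fold change of -0.36 and Apoe of -0.22.

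The effect of the genotype on C4b differed between oligodendrocytes and astrocytes. The difference was 2.39 on the log2 scale (SE 0.30; edgeR interaction test, adjusted p = 1.43e-06) and 2.22 without knockout replicate 1 (edgeR adjusted p = 7.95e-08). This test called 5 of 9404 genes, 4 with a higher effect in oligodendrocytes. The other 4 depended on knockout replicate 1, with an edgeR adjusted p of 1 without it. Between excitatory and inhibitory neurons the same edgeR test called 0 of 13196 genes (580 with an unadjusted p under 0.05); DESeq2 was not run on these differences.

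Oligodendrocyte precursors had no called gene (edgeR 0 of 3248, 223 with an unadjusted p under 0.05; DESeq2 0). The 5 smallest p were those of Arid5b (47.1 ± 6.11 against 130 ± 37.8 CPM, log2 1.504), Tmem131 (1.73), the calcium channel gene Cacna1c (1.83), the potassium channel gene Kcnq3 (2.44) and Plekha6 (1.56, and 1.28 to 2.11 with 1 library left out), each with an edgeR adjusted p of 0.677. The values of Cacna1c and Kcnq3 were 0.99 and 1.05 without knockout replicate 1. App and Apoe had log2 fold changes of -0.15 and -0.34, the latter between -0.94 and -0.012 with 1 library left out.

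In excitatory neurons, immediate early genes, which neuronal activity induces, fell as a group: 12 of 14 were lower (median -0.30; camera adjusted p = 0.0406; adjusted p = 0.989 with an estimated correlation). Fosb measured 15.2, 5.28 and 5.74 CPM in wild type and 1.77, 2.34 and 6.30 in knockout (log2 -1.47, and -2.12 to -0.78 with 1 library left out). Arc measured 49.4, 41.3 and 18.6 against 12.5, 7.95 and 39.6 CPM (log2 -0.91, and -1.83 to -0.53). For both genes knockout replicate 3 lay within the wild-type range, and for Arc wild type replicate 3 lay with the other 2 knockout libraries. Without knockout replicate 1 the call was lost (7 of 14 lower, median -0.061, camera adjusted p = 0.236). In striatal projection neurons the same list went the other way, with 10 of 11 higher over 6 libraries (camera adjusted p = 0.195) and a rise over the 5 of one version (11 of 13 higher, median 0.62, camera adjusted p = 0.00781, and 0.996 with an estimated correlation). There Fosb measured 2.88 ± 2.04 against 7.29 ± 4.20 CPM (log2 1.52) and Btg2 6.12 ± 1.77 against 13.8 ± 9.05 (1.23, and 0.52 at the lowest when 1 library was left out). In inhibitory neurons a list made for microglia, the Trem2-independent disease-associated genes, fell (6 of 7 lower, median -0.54; camera adjusted p = 0.00893; adjusted p = 0.989 with an estimated correlation); the members with the smallest p were the class I antigen genes B2m (18.2 ± 5.01 against 8.72 ± 1.37 CPM, log2 -1.11) and H2-D1 (32.3 ± 6.92 against 20.0 ± 5.28, log2 -0.71). Cholesterol synthesis genes also fell there (15 of 17 lower, median -0.32; camera adjusted p = 0.0220; adjusted p = 0.989 with an estimated correlation), but the call was lost without knockout replicate 1 (15 of 18 lower, median -0.16; camera adjusted p = 0.281).

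No single gene passed in a neuronal class over 6 libraries. edgeR called 0 of 12806 in excitatory, 0 of 10127 in inhibitory and 0 of 11538 in striatal neurons (620, 656 and 494 with an unadjusted p under 0.05), and DESeq2 0 in each. In excitatory neurons the smallest p belonged to the class I gene H2-T23 (21.3 ± 5.41 against 5.39 ± 3.02 CPM, log2 -1.95), 12.3 megabases from Trem2, followed by Adamts16 (1.72), Adnp2 (1.32) and Zfp46 (1.24), with an edgeR adjusted p of 0.665. In inhibitory neurons L3mbtl2 (1.47), Jade3 (1.52) and Lypd6 (2.04, and 1.41 without knockout replicate 1) had an edgeR adjusted p of 0.646. In striatal neurons H2-T22 (16.1 ± 0.606 against 4.80 ± 2.44 CPM, log2 -1.70), Pax6 (-1.57) and Cotl1 (1.86) had an edgeR adjusted p of 0.751. Reads can be shared within the H2-T family, whose members are similar in sequence, so their values are uncertain. Chosen after its values were seen, the interneuron peptide gene Sst measured 1719 ± 414 against 694 ± 280 CPM in inhibitory neurons (log2 -1.31, edgeR adjusted p = 0.646). With 1 library left out its log2 fold change was -1.64 to -1.04. The log2 fold changes of App were 0.15, -0.013 and 0.20 in the 3 neuronal classes.

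Summed over all nuclei, edgeR called 0 of 16425 genes (620 with an unadjusted p under 0.05) and DESeq2 0. Trem2 had a log2 fold change of -1.37 (edgeR adjusted p = 0.699). The smallest p were those of Guca1b, H2-T23, Crhbp, Ifi207 and Zcchc14, each with an edgeR adjusted p of 0.699. Guca1b, a photoreceptor calcium sensor 0.961 megabases from Trem2, was at 1.15, 0.985 and 1.12 CPM in wild type and 0, 0 and 0.0724 in knockout. Zcchc14 was at 42.8 ± 0.748 against 73.5 ± 2.91 CPM (log2 0.78), the interferon-inducible Ifi207 at 0.567 ± 0.109 against 1.56 ± 0.128 (1.45), and Crhbp, which binds corticotropin-releasing hormone, at 14.2 ± 3.88 against 5.81 ± 0.957 (-1.28).

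**Figure D3:**
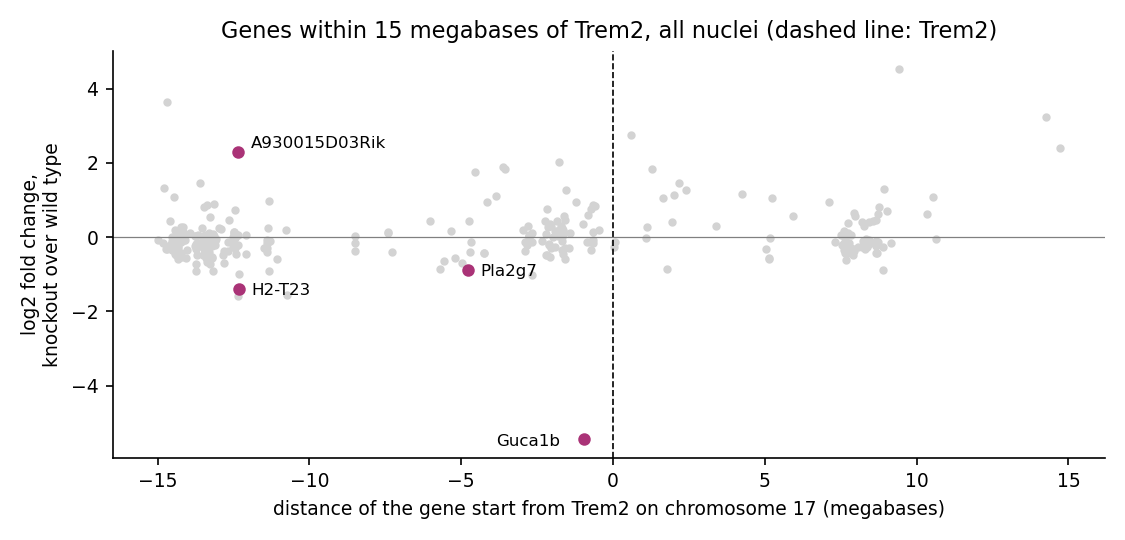
Log2 fold change of knockout over wild type summed over all nuclei (vertical axis) against distance from Trem2 in megabases (horizontal axis) for tested genes on chromosome 17; each point is 1 gene and coloured, named points have an unadjusted edgeR p under 0.01. The 4 named genes are Guca1b, Pla2g7, H2-T23 and A930015D03Rik, all at lower coordinates than Trem2.

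Class shares were set against an exact permutation test that cannot give a p under 0.1 with 3 libraries per genotype, so none of them could pass. Only oligodendrocytes had shares of all remaining nuclei that did not overlap between genotypes. They made up 13.03%, 12.8% and 12.4% of wild-type and 16.9%, 15.8% and 15.3% of knockout nuclei (12.7% ± 0.336 against 15.99% ± 0.792). The exact permutation test, two-sided, gave p = 0.1, the smallest possible, and 0.873 adjusted over classes. With 3 against 3 libraries a class shows no overlap by chance in 10% of cases. As a share of glial and vascular nuclei alone, oligodendrocytes overlapped between genotypes. Microglia made up 3.47% ± 0.894 and 5.34% ± 1.04 (exact permutation p = 0.2), astrocytes 3.62% and 3.09% (0.6), oligodendrocyte precursors 2.37% and 2.78% (0.4), excitatory neurons 18.98% and 18.99% (1), inhibitory neurons 6.42% and 5.71% (0.6) and striatal projection neurons 15.2% and 13.7% (0.8). Nuclei left unnamed were 35.8% ± 10.0 and 32.4% ± 2.59. Most nuclei of knockout replicate 1 in 3 classes fell into clusters of their own: clusters 8 and 20 of the excitatory neurons (98.9% and 98.8% from that library), cluster 21 of the striatal neurons (100%) and cluster 10 of the oligodendrocytes (93.8%). The other libraries held clusters 2 and 11, 0 and 1 of those classes. Vessel cells were too few to compare, at 8, 0 and 4 endothelial nuclei in wild type and 12, 2 and 5 in knockout, and 3, 5 and 8 against 21, 3 and 16 mural nuclei.

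**Figure D4:**
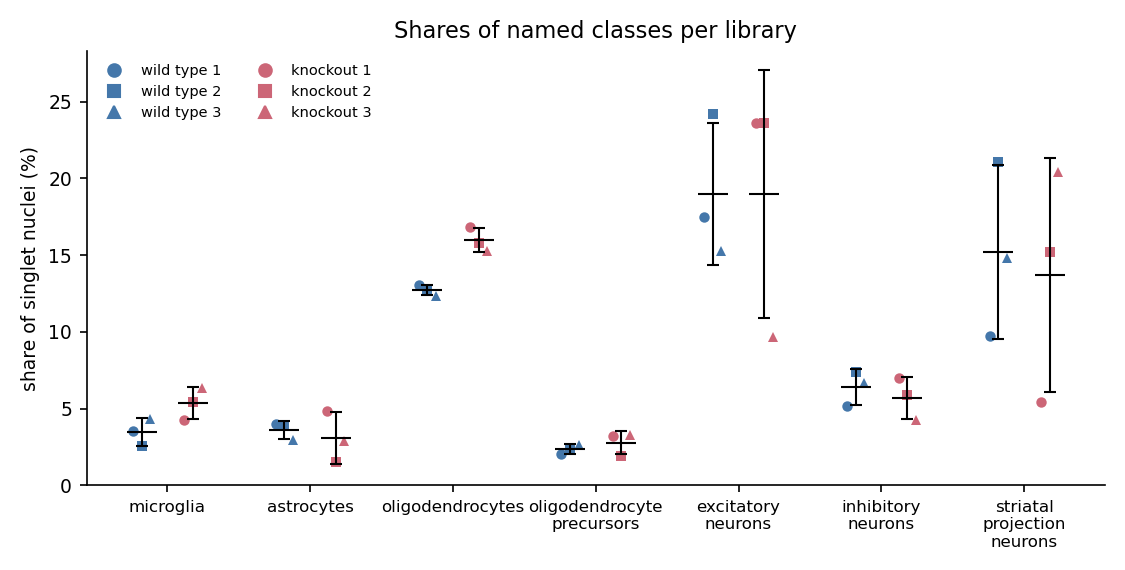
Share of singlet nuclei (vertical axis, percent) in each named class (horizontal axis) per library; symbols mark replicates and black bars the mean and SD of 3 libraries. The oligodendrocyte shares of the knockout (15.3% to 16.9%) lie above those of the wild type (12.4% to 13.03%), and the other classes overlap between genotypes.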

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

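The comparison of the genotype effect between classes was planned; every test of an explanation in this part was chosen after the result was seen. That comparison set 5 genes apart between oligodendrocytes and astrocytes (edgeR interaction test, 9404 genes, 500 with an unadjusted p under 0.05). C4b differed by 2.39 on the log2 scale, positive when the effect is higher in oligodendrocytes. In CPM before TMM scaling it was 129, 143 and 103 in wild-type and 194, 785 and 551 in knockout oligodendrocytes, against 159, 201 and 105 and 39.4, 231 and 149 in astrocytes. Ttc23 differed by 6.66, a fitted value that sets no bound, since wild-type oligodendrocytes had 0 UMIs in every library; knockout oligodendrocytes had 51.1 CPM in replicate 1 and 1.48 and 1.71 in the others. Arhgap24 differed by 3.32, with 91.7 CPM in the oligodendrocytes of knockout replicate 1 and 6.89 to 19.3 in the other libraries. Tubb3 differed by 2.72, with 180 CPM in that library's oligodendrocytes and 42.7 to 68.4 in the others. Pde4d differed by -2.91, with 571 CPM in that library's astrocytes and 0 to 22.97 in the others. Without knockout replicate 1 the differences of these 4 genes were 3.99, 0.90, 1.14 and -0.99, with an edgeR adjusted p of 1, and that of C4b was 2.22. The 10 splits of 6 libraries are too few for a share under 0.05; 4 of them gave at least as many calls, with 5 in the real split and 13 as the highest other.

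C4b was higher in the oligodendrocytes of every knockout library, and in astrocytes it was not. At least 1 C4b UMI was found in 14.1%, 18.4% and 12.2% of wild-type and 10.8%, 24.6% and 18.6% of knockout astrocytes. By that measure knockout replicates 2 and 3 lay above every wild-type library, replicate 3 by little. Their astrocytes held only 22 and 26 C4b UMIs. A chromosome segment around Trem2 that acts on C4b alike in every class is argued against by the difference between both classes (adjusted p = 1.43e-06), though a segment that acts in some classes stays open. In microglia C4b was at 0, 9.68 and 0 CPM in wild type and 19.8, 30.1 and 9.52 in knockout, from at most 10 UMIs per library. Knockout replicates 1 and 2 were thus higher there, and replicate 3 overlapped with wild type. In the precursors of knockout replicate 2 it was at 209 CPM, against at most 42.5 in wild type. Knockout replicates 2 and 3 were higher in striatal neurons (8.74 and 2.95 CPM, against at most 1.90 in wild type) and excitatory neurons (3.32 and 2.64, against at most 1.785). Inhibitory neurons overlapped (3.90, 5.24 and 0 against 1.18, 3.49 and 5.07 CPM). RNA free in the droplets would raise C4b in every class alike, whereas outside astrocytes no class reached more than 0.266 of the oligodendrocyte CPM in knockout replicates 2 and 3. A reaction of oligodendrocytes that takes in genes outside chromosome 17 is a candidate explanation: 6 such members of the disease-associated list, 5 of them higher, had a median log2 fold change of 0.56 without knockout replicate 1 (2 with an unadjusted p under 0.05), and 4 tested members had 0.25 over 6 libraries. Loss of Trem2, a difference in amyloid between the mice and the background strain were not told apart by any value here.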

How the results depend on the processing

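Calls over 6 libraries depended on the filter and on knockout replicate 1. With every gene of at least 1 count, edgeR called 242 genes in microglia, 509 in astrocytes, 314 in oligodendrocytes and 444 in oligodendrocyte precursors, and Trem2 in microglia passed (log2 -1.48, edgeR adjusted p = 0.00647; 0.0670 to 0.992 under the other alternatives); the neuronal classes and all nuclei kept 0 calls. Those 4 counts were nearly all rises. The calls included the intron-rich genes Csmd1 in microglia and Rbfox1 in oligodendrocyte precursors, which over all nuclei were high in knockout replicate 1 only. Csmd1 was at 5153 CPM there and 348 to 497 elsewhere. How many of these calls rest on that library was not tested, so they cannot be read as knockout effects. DESeq2 on the 5 libraries of one version called 1 gene in oligodendrocytes (C4b), 2 in excitatory neurons (Hba-a1 and H2-T24), 1 in striatal neurons (H2-T24) and 8 over all nuclei, an alternative chosen after seeing the data; fewer libraries were used. Other size factors, kept doublets, the stricter filter, sex-linked genes left out, finer clustering, thinning, and genes with under 2000 intron bases gave 0 calls in every class they covered; finer clustering does not change the sum over all nuclei. The interaction of astrocytes and oligodendrocytes called 1 gene after thinning, with 2261 genes tested. camera with an estimated correlation and fry each called 0 lists.

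Leaving out 1 library at a time gave 0 to 2 calls in microglia, 0 to 1 in oligodendrocytes and 0 in the other classes. It gave 2 to 46 calls between astrocytes and oligodendrocytes (2 without knockout replicate 1 or wild type replicate 3, 39 and 46 without knockout replicates 2 and 3), 0 to 7 between excitatory and inhibitory neurons, and 2 to 37 gene lists. Trem2 in microglia stayed between -1.91 and -1.27. Differences in class shares in percentage points ranged from 1.38 to 2.42 (microglia), 2.83 to 3.61 (oligodendrocytes), -1.41 to 0.258 (astrocytes), 0.172 to 0.850 (precursors), -2.32 to 4.66 (excitatory), -1.34 to 0.0232 (inhibitory) and -4.86 to 2.65 (striatal). Log2 fold changes changed sign for Apoe in astrocytes (-0.59 to 0.10), microglia (-0.22 to 0.59) and oligodendrocytes (-0.57 to 0.15), for App in excitatory neurons (-0.14 to 0.39), inhibitory neurons (-0.18 to 0.16), precursors (-0.43 to 0.066) and oligodendrocytes (-0.069 to 0.28), for C4b in astrocytes (-0.91 to 0.063) and for Gm26917 in microglia (-0.25 to 2.41).

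Signs also reversed elsewhere, with causes not tested. Astrocyte shares differed by 0.362 under the stricter filter and 0.442 without wild type replicate 1 and knockout replicate 2, excitatory shares by -1.52 and -3.06 and by -0.419 with finer clustering, and precursors by -0.657 as a share of glial and vascular nuclei. The homeostatic score was higher by 1.31 genes after thinning, which kept 11, 8 and 24 wild-type and 268, 43 and 25 knockout nuclei. By DESeq2 on 5 libraries C4b and Apoe in astrocytes were at 0.10 and 0.12, App and Apoe in oligodendrocytes at -0.065 and 0.15, and App in excitatory neurons at -0.14. Low-intron genes put Apoe at 0.019 in astrocytes and 0.15 in oligodendrocytes. Apoe in oligodendrocytes was at 0.032 with doublets kept and 0.17 under the stricter filter, which put App in precursors at 0.031. App in inhibitory neurons was at 0.0033 after thinning and 0.022 with finer clustering. No paired analysis was possible because replicate numbers follow accession order only. Endothelial and mural cells were not run, with under 20 nuclei in some libraries.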

Other observations

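The tests in this part were chosen after the results were seen, apart from the counts of splits and the gene lists. H2-T24, a class I histocompatibility gene whose reads can be shared within its family, measured 14.99 ± 4.80 in wild-type and 3.04 ± 4.24 CPM in knockout striatal neurons (log2 -2.43). Its log2 fold change there was -4.72 without knockout replicate 1 (edgeR adjusted p = 0.133). In excitatory neurons it was at 13.1, 8.89 and 18.2 CPM in wild type and 10.1, 1.87 and 1.35 in knockout, so knockout replicate 1 lay within the wild-type range (log2 -1.44, and -2.96 without that library). In inhibitory neurons Npy measured 929 ± 182 against 478 ± 255 CPM and Crhbp 124 ± 16.5 against 56.3 ± 24.8. With 1 library left out their log2 fold changes were -1.24 to -0.575 and -1.48 to -0.86. Both are transcripts of the kind of interneuron that expresses Sst. The cluster led by Sst and Npy held 55, 104 and 103 of 266, 411 and 389 inhibitory nuclei in wild type. In knockout it held 153, 71 and 52 of 520, 271 and 188, so its share was not lower there. The haemoglobin gene Hbb-bs was high in single libraries, at 197 CPM over all nuclei in knockout replicate 2, 10.1 in replicate 3 and at most 1.58 elsewhere. In excitatory neurons of knockout replicate 2 it was at 514 CPM and Hba-a1 at 233, above the 89.5 of Hba-a1 over all nuclei, and where these transcripts came from was not tested.

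Without knockout replicate 1 cholesterol synthesis rose in excitatory neurons, with 14 of 19 higher (camera adjusted p = 0.000887). Ribosomal protein genes rose in excitatory (20 of 21 higher, camera adjusted p = 0.0225) and striatal neurons (21 of 21, camera adjusted p = 0.00131), and mitochondrial transcripts in striatal neurons (10 of 10, camera adjusted p = 0.0212); each had an adjusted p of 0.996 with an estimated correlation. In border macrophages Trem2 had 5, 7 and 9 UMIs in wild type and 4, 1 and 5 in knockout. An unnamed cluster led by Lgr5 and Vipr2 held 21.7% of wild type replicate 1 and 14.8% of knockout replicate 2 but at most 2.44% of any other library. Other unnamed clusters had the same pattern. One led by Zic1 and Trh held 4.68% and 5.27% of these libraries (at most 1.175% elsewhere). A cluster led by ribosomal protein genes held 2.56% and 1.33% (at most 0.172% elsewhere), and one led by Sash1 and Fabp7 0.561% and 0.414% (0% elsewhere). Class shares and sums over all nuclei move with such clusters. The cause was not tested. In endothelial nuclei Cldn5 had 83, 0 and 21 UMIs in wild type and 28, 3 and 12 in knockout, of 12657, 0, 3419, 18205, 1557 and 4339 in all. In mural nuclei Vtn had 11, 40 and 45 against 241, 11 and 120, of 1956, 5935, 7999, 47548, 1960 and 12645.

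Knockout replicate 1 differed from the other 5 libraries in every class. Counting of intronic reads in that library and not in the others is a candidate explanation: the gap between genes rich and poor in intron was 1.81 on the log2 scale in its oligodendrocytes and at most 0.26 elsewhere. Its greater depth is argued against, since thinning every library to the same total left its mean correlation with the others at 0.786. Loss of Trem2 is argued against by the same gap in knockout replicates 2 and 3, which was at most 0.143 of that in replicate 1. Which settings the software was run with was not tested and is not given in the sources used here.

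Genes near Trem2 were frequent among the smallest p over all nuclei. Within 15 megabases on either side lay 4 of the 14 genes with p under 0.01 (Trem2 not being among them) but only 297 of the 16417 tested, a ratio of 15.8 (Fisher's exact p = 9.11e-05, over genes, which are not independent); 1.35% of the window's genes had such a p, against at most 1.06% in 91 other windows. By class the window held 3 of 23 such genes in oligodendrocytes (ratio 7.64) and 3 of 10 in striatal neurons (ratio 17.1). It held 1 of 17 in excitatory neurons (ratio 3.35, Fisher's exact p = 0.260), 1 of 24 in inhibitory neurons (ratio 2.54, Fisher's exact p = 0.328), 1 of 50 in astrocytes (ratio 1.33, Fisher's exact p = 0.533), 0 of 22 in microglia and 0 of 12 in precursors. A segment of another strain carried along with the knockout allele is a candidate explanation. Guca1b lay at 0.961 megabases, Pla2g7 at 4.78 (25.4 ± 3.16 against 13.7 ± 2.54 CPM) and H2-T23 and A930015D03Rik about 12.3 away. A930015D03Rik had 51, 62 and 79 UMIs over all nuclei in wild type and 1796, 127 and 199 in knockout. Its count was thus carried mainly by knockout replicate 1 (log2 2.29, and 1.31 to 2.64 with 1 library left out). For all nuclei the ratio was 13.4 without H2- genes (Fisher's exact p = 0.00127). The share of the window's genes then equalled that of the highest other window, 1.06% each. Among the 3 genes left, A930015D03Rik (35994453 to 36038435) spans H2-T24 and H2-T23, so the filter did not remove that locus. A change of histocompatibility genes alone does not cover Guca1b and Pla2g7. No ratio was computed without A930015D03Rik, so that explanation stays open for all nuclei. In oligodendrocytes 3 of 23 were left without H2- genes. In striatal neurons 1 of 8 was left (Fisher's exact p = 0.129) and in excitatory neurons 0 of 16, so for these neurons that explanation stays open as well. The processing of knockout replicate 1 is argued against by a ratio of 7.51 without it, with 2.61% of the window's genes against at most 2.11% elsewhere; without H2- genes as well it was 2.07% against 2.11%. Strain, allele history and an effect of Trem2 loss on these genes stay open.

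The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For each class and for all nuclei 10 of 10 splits gave at least the 0 calls of the real one; the highest other count was 0, except for 1 in oligodendrocytes. Between excitatory and inhibitory neurons it was 10 of 10, with 0 calls in the real split and 9 as the highest other. Of the gene list tests the real split called 8, at least as many came from 8 of 10 splits, and the highest other called 49. That split set wild type replicates 1 and 2 and knockout replicate 3 against the rest, which points to a structure of the samples other than genotype. These 3 libraries had a negative gap between genes rich and poor in intron in oligodendrocytes (-0.21, -0.11 and -0.17; 0.20, 1.81 and 0.26 in wild type replicate 3 and knockout replicates 1 and 2) and the highest shares of barcodes above 5% mitochondrial UMIs (15.5%, 17.8% and 29.99% against 6.33%, 4.62% and 9.48%). The genotypes were not compared within these groups.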
